A study of Caenorhabditis elegans with 32 samples.

How the data were processed

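Small RNA was sequenced from whole Caenorhabditis elegans of 2 genotypes, wild type (WT) and hrde-1, a mutant of the germline nuclear Argonaute HRDE-1 that binds 22G RNA, the antisense small RNA made by RNA-dependent RNA polymerases. Each genotype was sampled at the parental generation P0 and at the descendant generations F1, F2 and F3, under a normoxia or a hypoxia label, with 2 libraries in each of the 16 groups and 32 libraries in all. Per the labels' protocols, L4 larvae were held at 0.1% oxygen for 16 h at 20 °C and then returned to ambient oxygen near 20%. The hypoxia label is carried by every generation and the labels do not say which generations were exposed. Hypoxia at F1 to F3 is taken here, as an assumption from background knowledge, to mean descent from exposed P0 animals. RNA was isolated with a mirVana kit, 500 ng was treated with the pyrophosphohydrolase RppH at 37 °C for 30 min so that molecules with a 5′ triphosphate could be captured, and libraries were made with the Nextflex Small RNA-seq v3 kit. Reads were 85 bp long, per the labels.

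The deposited tables held counts per feature for 4 classes: 22G RNA by gene (46932 genes), microRNA (390 features), piRNA (13664 features) and snoRNA (345 features). Per the submitters' processing notes, FastQC, cutadapt 2.5, featureCounts and edgeR were used on these data. The aligner, the genome build, the annotation and the strand setting of the counting were not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as F44E5.4 and F44E5.5, could not be told apart. The deposited values were whole counts except in the F2 WT normoxia libraries, where 22G, miRNA and piRNA values were partly fractional. For 22G RNA 24.5% and 23.6% of the values of those libraries were fractional, each a multiple of 1/3. These values were treated as deposited expected counts and rounded to whole numbers. Apart from those libraries, the miRNA and piRNA tables held no value between 0 and 5, so a feature at 0 there is only listed at 0 and no fold is given. Of the 22G genes, 46919 matched WBcel235 gene identifiers, from which symbols and coordinates were taken, and 24108 had no count in any library. The 5 summary entries of the 22G table were kept out of library sizes and tests.

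Depth was 438436 to 2578063 counts per library for 22G RNA, 1368088 to 5848199 for miRNA, 215629 to 738793 for piRNA and 64647 to 218690 for snoRNA. No 2 libraries held identical values, and the replicate chi-square per degree of freedom was 1.45 or more (median 12.24), so each library counted as 1 replicate. The labels do not say that replicates were separate cultures, and p-values therefore measure only the spread between these samples, which may be technical.

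Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust glmQLFit, glmQLFTest) in R 4.3.3, with TMM scaling within each class table, filterByExpr by group with a minimum count of 10, Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. The test, the samples in each fit, the named genes and most alternatives were chosen before the data were examined. Single-generation comparisons and the interactions between hypoxia and genotype came from 1 fit over all 32 libraries with 16 group means. The comparisons pooled over F1 to F3 within a genotype (6 against 6 libraries) and between genotypes under normoxia (8 against 8) added the generation as a term. Log2 fold changes are given with their standard error (SE), and adjusted p-values are edgeR's unless another tool is named. CPM are counts scaled to a common library total after TMM scaling, with a prior count of 2 for plots on a log scale. The share of each class in the sum of the 4 class totals was compared with a two-sided exact permutation test within generations over 1296 arrangements, which cannot give a p below 0.0015.

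Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. For 22G RNA they were heat shock proteins, hypoxia response, small RNA machinery, ERGO-1 class targets, spermatogenesis genes, oogenic and maternal genes, histones, histone modifiers, ribosomal proteins, ribosomal RNA, collagens and cuticle, vitellogenins and intestine, neurons, embryo and early larva, muscle, lipid metabolism, F-box genes, MATH and BATH genes, C-type lectins, chemoreceptors, nuclear RNAi targets and the pair F44E5.4 and F44E5.5. For miRNA they were the let-7, lin-4, mir-35, mir-44, mir-51, mir-58, mir-64 and mir-2 families, tissue miRNAs and miRNAs of stress and ageing. Lists with fewer than 5 tested members were counted but not tested as sets. Mitochondrially encoded genes, daf-21 and hph-1 matched no symbol and were not analysed here.

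The text names hrde-1, F44E5.4 and F44E5.5 in every 22G comparison. For P0, pooled and genotype comparisons it names up to 6 genes higher and 6 lower, by largest change among those past the threshold, with a mean of at least 10 CPM in the higher group and every library of one group above every library of the other within each generation. For single descendant generations and interactions the limit was 3 and 3, for miRNA 4 and 4, and for piRNA and snoRNA 2 and 2. Separation of libraries is not defined for an interaction and was not applied there. Where nothing passed, the 2 features with the smallest p are named, and each list adds up to 4 members. Other genes named, such as genes shared between generations or the members behind a count, were chosen after their values were seen. A fold against a group whose libraries were all at 0 is given as at least N-fold, against a floor of 3 counts per library, and such floors cover counting error only.

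The alternatives were DESeq2 size factors, the sum of the 4 classes as library size without TMM, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, only the compared libraries in the fit, each library left out, fry and an estimated correlation for lists, and other denominators for class shares. After the data were seen, fits without one generation and fits of genes with a mean of at least 10 CPM were added. The fits were tested on simulated counts. With 100 of 10121 22G genes changed at each size in the P0 WT comparison, 5% of those at a log2 change of 1 and 11% of those at 2 were recovered. The F1 to F3 WT comparison recovered 50% and 79% over 8485 genes, and the genotype comparison 16% and 62% over 9279 genes. Plots were drawn with matplotlib 3.10.9, and tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.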

Results

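The study asked whether small RNA changes that follow hypoxia are inherited by later generations and whether they depend on HRDE-1, the germline nuclear Argonaute. Counts of 4 classes of small RNA were deposited for whole worms, with 2 libraries for each combination of genotype (WT or hrde-1), oxygen label (normoxia or hypoxia) and generation (P0, F1, F2 or F3). The 4 classes together held 2595534 to 7127495 counts per library. At an equal depth of 400000 counts, the F3 hrde-1 normoxia libraries would show 7097 and 6018 genes with 22G RNA. The F3 hrde-1 hypoxia libraries would show 8708 and 8307, the F3 WT normoxia libraries 10484 and 10236 and the F3 WT hypoxia libraries 8393 and 9450. The first principal component of 22G counts held 35.6% of the variance and separated the genotypes. Log2 fold changes below are hypoxia against normoxia unless said otherwise, ± SE. Single generations had 2 libraries per group and F1 to F3 together had 6, which may not be 6 independent lines.

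MicroRNA took a smaller share of the small RNA of WT animals under hypoxia, 48.2% ± 3.53 (SD, n = 8) against 61.2% ± 12.5 under normoxia (two-sided exact permutation p = 0.0015, the smallest possible, adjusted p = 0.0185 over 12 tests). The difference had the same sign in every generation, from -36.5 percentage points at P0 to -3.23 at F1, -4.03 at F2 and -8.11 at F3. The P0 value, the largest, rests on normoxia libraries whose preparation may have differed (see the flagged results). No P0 WT comparison below can separate that from hypoxia. The 22G share was 38.6% ± 4.95 against 28% in WT (exact permutation p = 0.0417, adjusted p = 0.25) and did not pass the adjustment. At P0 the 22G share was 7.71% ± 2.21 (SD, n = 2) in WT normoxia and 42.2% ± 1.48 in WT hypoxia. In P0 hrde-1 it was 38.5% ± 2.53 and 45.4% ± 0.78. In hrde-1, hypoxia moved the 22G share by 1.16 points (exact permutation p = 0.724) and the miRNA share by -2.25 points (p = 0.424). Between the genotypes under normoxia the 22G share differed by 6.24 points (exact permutation p = 0.227). The piRNA and snoRNA shares passed in none of these comparisons, with p of 0.0756 or more. Of the 12 tests 2 had an unadjusted p below 0.05. This was 1 without the F1 WT hypoxia 2 library, the F2 WT hypoxia 1 library or any single F3 WT library, and 3 without F1 WT normoxia 2.

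**Figure D1:**
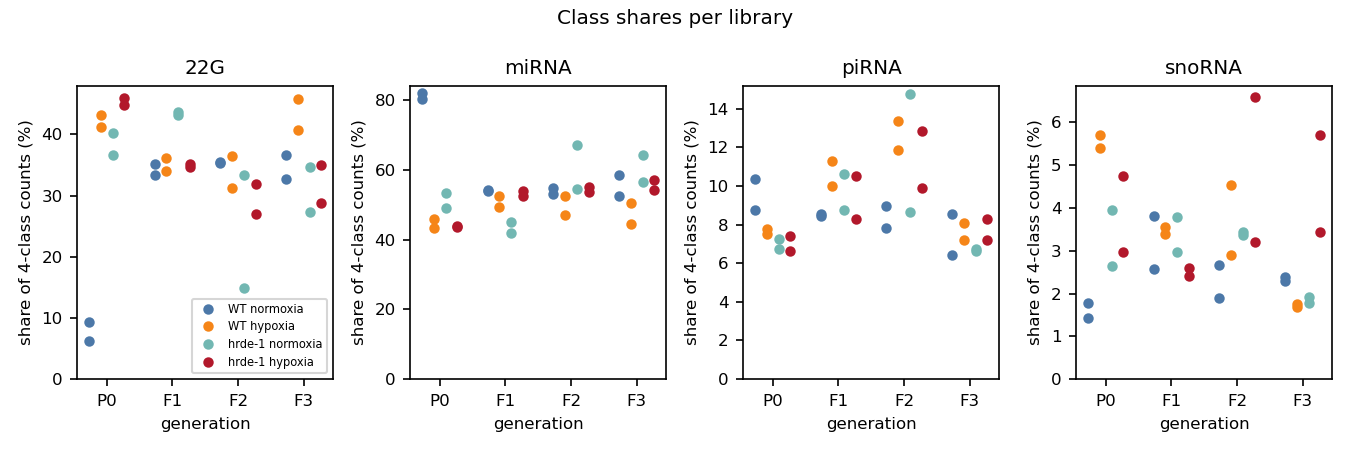
Share of each small RNA class in the sum of the 4 class totals (%, vertical axes starting at 0) by generation, with 1 point per library and colours for genotype and oxygen label. The P0 WT normoxia libraries have the lowest 22G shares (mean 7.71%) and the highest miRNA shares (mean 81.1%).

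In the hrde-1 gene itself (III:4172337-4176159, WBcel235) WT normoxia libraries averaged 392 to 459 CPM per generation and hrde-1 normoxia libraries 292 to 482, a log2 difference of -0.28 ± 0.15 (adjusted p = 0.177, n = 8 per genotype). Counts of 22G RNA antisense to a gene do not report its own transcript, so they do not check the genotype. With the sum of the 4 classes as library size the difference was 0.05. Under hypoxia hrde-1 22G counts did not pass in any comparison, with 0.33 ± 0.09 (adjusted p = 0.055) for F1 to F3 WT and 0.49 ± 0.20 (adjusted p = 0.554) at P0 WT.

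F44E5.4 (II:11757107-11759311) and F44E5.5 (II:11759662-11761861), a divergent, near-identical hsp-70 family pair sharing reads, had few 22G counts. F44E5.4 averaged 4.65 ± 2.23 CPM (SD, n = 2) in P0 WT normoxia and 20.0 ± 1.09 in P0 WT hypoxia. The log2 fold changes of F44E5.4 and F44E5.5 in WT were 2.14 ± 0.81 and 1.92 ± 0.81 at P0 and 1.86 ± 0.66 and 1.93 ± 0.65 at F1. They were -0.20 ± 0.69 and -0.56 ± 0.69 at F2 and 1.61 ± 0.66 and 1.92 ± 0.68 at F3. None passed over all genes in the main fit (lowest adjusted p 0.202). Nor did the pair for F1 to F3 WT (1.17 ± 0.39 and 1.19 ± 0.40, adjusted p = 0.0991 and 0.104). In hrde-1 both passed at F3 alone, at 2.94 ± 0.73 and 2.78 ± 0.72 (adjusted p = 0.00634 and 0.00858). F44E5.5 did not without F3 hrde-1 hypoxia 2, and neither passed with only the compared libraries (adjusted p = 0.81 and 0.847). The interaction passed at no generation. With the 4-class library size both passed at P0 in WT and the interaction (medians 4.69 and -4.09, all genes 2.70 and -2.32). The pair is taken from background knowledge, not the labels, as chosen by the study on these samples, so its direction is not independent evidence.

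In P0 WT, 22G RNA against the small heat shock protein genes hsp-16.1 and hsp-16.11 rose by 2.33 ± 0.46 (adjusted p = 0.00694) and 1.76 ± 0.42 (adjusted p = 0.0457), 2 of the 21 heat shock genes measured. Neither F44E5 gene passed. Targets of the ERGO-1 Argonaute pathway, which makes small RNA against recent duplications and non-coding loci, fell. Of 18, 7 were called lower, 13 adjusted over the list alone, among them cel-mir-8199 (-3.69 ± 0.78, adjusted p = 0.0145), F39F10.4 (-2.76 ± 0.51), F39E9.7 (-2.67 ± 0.43) and T08B6.2 (-1.78). Also lower were the non-coding RNA gene T09B4.14 (-4.85 ± 0.47, adjusted p = 4.49e-07), F10C2.11 (-4.58 ± 0.56), F55C9.3 (-3.56 ± 0.57), T05E11.9 (-3.39 ± 0.47) and T28B8.1 (-3.31 ± 0.42). Counts on the 5.8S ribosomal RNA gene rrn-2.1 rose by 3.89 ± 0.89 (adjusted p = 0.0313). Other rises were in ZC317.6 (3.00 ± 0.65), the peroxisome biogenesis gene prx-11 (2.61 ± 0.44), ZK858.8 (2.37 ± 0.48) and C14C11.1 (2.23 ± 0.49). The F-box genes fbxa-61 (-2.02) and fbxa-52 (-1.82) fell.

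As sets at P0 WT, ERGO-1 targets were lower (median -1.37, camera adjusted p = 1.38e-22, adjusted p = 0.00267 with an estimated correlation). Histone genes were higher (57 genes, median 0.88, adjusted p = 2.19e-08, adjusted p = 0.00267 with an estimated correlation). Of these 0 were called one by one and 2 adjusted over the list alone. The 4-class library size called 51 of them higher, with 21 heat shock, 11 hypoxia response, 30 collagen and 9 spermatogenesis genes. Heat shock genes were higher (median 0.72, adjusted p = 6.04e-06, 3 adjusted over the list alone). Ribosomal RNA genes were higher too (8 genes, 1 called, 5 adjusted over the list alone, median 1.90, adjusted p = 5.09e-07). Hypoxia response genes were higher (14 genes, 0 called, 2 adjusted over the list alone, median 0.81, adjusted p = 0.0186). So were collagens (43 genes, median 0.30, adjusted p = 0.0168), and spermatogenesis genes were lower (49 genes, median -0.45, adjusted p = 0.0168). With an estimated correlation heat shock to spermatogenesis genes, in turn, had adjusted p = 0.0897, 0.0563, 0.0563, 0.135 and 0.0897. The other lists tested did not pass (adjusted p from 0.142 to 0.739).

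In all, 71 of 10121 genes passed at P0 WT, 17 higher and 54 lower, against the normoxia libraries flagged below. T09B4.14, F10C2.11, T05E11.9 and T28B8.1 stayed past the threshold whichever compared library was left out, while hsp-16.1 did not without P0 WT normoxia 2 or P0 WT hypoxia 1 (adjusted p up to 0.259). The count fell with each library left out and was 207 (83 higher, 124 lower) without the F3 libraries. With the sum of the 4 classes as library size the median of all genes moved from 0.05 to 2.70 and 7496 genes passed, 7494 of them higher. The ERGO-1 median then became 1.33 (11 of 18 called higher, 0 lower), or -1.36 relative to all genes, and the spermatogenesis median 1.46. Neither the ERGO-1 nor the hypoxia response list passed there (adjusted p = 0.61 and 0.868).

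In P0 hrde-1, most of the change was again downward, 64 of 72 calls. The ERGO-1 targets E01G4.5 (-3.76 ± 0.57, adjusted p = 0.00113), cel-mir-8199 (-4.41 ± 0.83), F39E9.7 (-2.30 ± 0.42) and E01G4.7 (-1.92 ± 0.31) fell, 5 of 18 called and 12 adjusted over the list alone. The long intergenic non-coding RNA genes linc-121 (-7.17 ± 1.44, adjusted p = 0.00909) and linc-12 (-4.40 ± 0.69), the F-box genes fbxa-53 (-5.61 ± 1.29), fbxa-61 (-3.04 ± 0.47) and fbxa-52 (-2.61 ± 0.38) fell with them. So did Y51A2A.16 (-5.52 ± 0.86) and Y116F11A.1 (-4.64 ± 0.60, adjusted p = 9.91e-05). Y18D10A.22 (4.52 ± 0.89, adjusted p = 0.0107), H06O01.4 (1.72 ± 0.39), Y73E7A.8 (1.66 ± 0.31), lido-15 (1.34 ± 0.28) and the chemoreceptor genes srd-72 (1.60 ± 0.38) and srd-71 (1.49 ± 0.35) rose. The ERGO-1 list was lower (median -1.05, adjusted p = 4.68e-16, adjusted p = 0.0157 with an estimated correlation). Ribosomal proteins (median -0.27) and MATH and BATH genes (median -0.21) were lower (both adjusted p = 0.0036, or 0.0533 and 0.171 with an estimated correlation). These medians turned to 0.09 and 0.16 with the 4-class library size. Spermatogenesis genes (median 0.78, adjusted p = 0.0233) and chemoreceptors (2 called higher, adjusted p = 0.0291) were higher (both 0.126 with an estimated correlation). Heat shock genes did not pass (adjusted p = 0.0819).

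Part of this rested on single libraries. E01G4.5 held 440 and 2140 CPM in the P0 hrde-1 normoxia libraries against 59.3 and 132 under hypoxia. The count of 72 fell to 20 without P0 hrde-1 normoxia 2, 20 without P0 hrde-1 hypoxia 1 and 47 without P0 hrde-1 hypoxia 2. Of the genes named by the rule only Y116F11A.1 and Y51A2A.16 passed in each such fit. A fit without the F3 libraries called 320, 121 of them higher, and the 4-class library size 41 (7 higher, 34 lower; median of all genes 0.43). Of the chemoreceptors 0 passed there and the list did not (adjusted p = 0.143).

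The 2 genotypes shared 34 genes called lower at P0, where independent lists would share 0.341, and none called higher. Under the 4-class library size, where P0 WT had 2 genes lower and 7494 higher, they shared 0 lower and 7 higher (independent lists would share 5.18). Over 10121 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.244. The response differed between the genotypes for 6 genes by the interaction test (5 more positive in hrde-1). T09B4.14 (difference 3.75 ± 0.60, adjusted p = 0.00788), T28B8.1 (3.23 ± 0.52, adjusted p = 0.00788) and cel-mir-5592-2 (3.01 ± 0.55) fell more in WT. In contrast prx-11 (-2.91 ± 0.53, adjusted p = 0.0199) rose in WT, from 7.18 ± 7.23 CPM (SD, n = 2) to 48.0, and not in hrde-1, where it held 274 in normoxia and 223 under hypoxia. Spermatogenesis genes (median difference 1.03, adjusted p = 2.78e-05) and histone genes (median difference -0.64, adjusted p = 3.03e-05) responded differently in the 2 genotypes (0.0135 and 0.0228 with an estimated correlation). The spermatogenesis median difference turned to -0.75 with the 4-class library size. The count of 6 was 0 without P0 WT normoxia 2, P0 WT hypoxia 1 or P0 hrde-1 normoxia 1, 3 without P0 WT hypoxia 2, 2 without P0 hrde-1 normoxia 2 and 20 without the F3 libraries. The 4-class library size gave 3919 (2 more positive, 3917 more negative; median of all genes -2.32).

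In F1 WT, 22G RNA against small heat shock protein genes was higher. hsp-16.49 (2.59 ± 0.44, adjusted p = 0.00691), hsp-16.48 (2.41 ± 0.40), hsp-16.1 (2.36 ± 0.41), hsp-16.11 (2.23 ± 0.39) and the chaperone gene hsp-110 (1.86) rose, 5 of 21 heat shock genes and 12 adjusted over the list alone. The 4 hsp-16 genes lie in near-identical pairs on chromosome V that share reads. hsp-16.1 held 34.8 ± 9.55 CPM (SD, n = 2) in F1 WT normoxia and 180 ± 7.93 in F1 WT hypoxia. linc-12 (-4.50 ± 0.74, adjusted p = 0.00775), Y116F11A.1 (-3.73 ± 0.60), the ERGO-1 target E01G4.5 (-3.15 ± 0.55, adjusted p = 0.016) and the F-box gene fbxc-18 (-1.82 ± 0.36) fell. The heat shock list was higher (median 1.41, adjusted p = 2.4e-28, adjusted p = 0.000523 with an estimated correlation). The ERGO-1 list was lower (median -0.73, 1 called and 11 adjusted over the list alone, adjusted p = 2.61e-20, adjusted p = 0.00318 with an estimated correlation). Ribosomal proteins (73 genes, median 0.36, adjusted p = 0.00102), small RNA machinery (median 0.17, adjusted p = 0.00192) and oogenic and maternal genes (adjusted p = 0.0215) were higher. F-box genes (188 genes, 1 called, median -0.35, adjusted p = 1.24e-05) and chemoreceptors (median -0.27, adjusted p = 0.0499) were lower. With an estimated correlation ribosomal proteins to chemoreceptors had, in turn, adjusted p = 0.0208, 0.139, 0.22, 0.0975 and 0.122. Of all genes 17 passed, 8 higher and 9 lower. The count was 0 without F1 WT normoxia 1, F1 WT hypoxia 1 or F1 WT hypoxia 2, 8 without F1 WT normoxia 2 and 77 without the F3 libraries. hsp-16.1, hsp-16.48, hsp-16.49 and E01G4.5 passed in none of the 4 fits with a library left out (adjusted p up to 0.274, 0.185, 0.251 and 0.532), and linc-12 and Y116F11A.1 only in that without F1 WT normoxia 2. The 4-class library size left 9, 1 of them higher, a heat shock gene (median of all genes 0.12), and 0 F-box genes.

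In F1 hrde-1 the pattern was another. B0524.4 (3.00 ± 0.48, adjusted p = 0.00213), VY10G11R.3 (4.64 ± 1.04) and C27A2.7 (2.36 ± 0.44) rose. F20D6.10 (-2.65 ± 0.48), the F-box gene fbxb-20 (-1.60 ± 0.36) and Y46G5A.6 (-1.2 ± 0.22) fell. The linker histone gene hil-8 rose by 1.44 ± 0.26 (adjusted p = 0.00783). The ERGO-1 list (median 0.20, adjusted p = 0.334) did not pass. Spermatogenesis genes were higher (median 1.28, adjusted p = 0.00945, adjusted p = 0.151 with an estimated correlation). By the interaction test the F1 response differed between the genotypes for heat shock genes (median difference -0.99) and ERGO-1 targets (1.2, both adjusted p = 9.37e-12). It also differed for spermatogenesis genes (1.87, adjusted p = 0.000648), each list at 0.024 with an estimated correlation. Under normoxia hrde-1 already differed from WT toward WT hypoxia (medians 0.73 for heat shock and -1.55 for ERGO-1 genes over all generations). A lost response thus cannot be told apart from a different starting level. Single genes with a different response were hsp-16.49 (-2.92 ± 0.59, adjusted p = 0.0468), B0524.4 (3.12 ± 0.62), Y26G10.5 (2.75 ± 0.53) and Y59E1A.4 (2.16 ± 0.34). The F1 hrde-1 comparison called 35 genes, 28 higher. The count was 2 without F1 hrde-1 normoxia 1, 2 without F1 hrde-1 normoxia 2, 12 without F1 hrde-1 hypoxia 1, 8 without F1 hrde-1 hypoxia 2 and 272 without the F3 libraries. VY10G11R.3, C27A2.7, F20D6.10 and fbxb-20 passed in none of these 4, B0524.4 only without a hypoxia library and Y46G5A.6 only without F1 hrde-1 hypoxia 2. DESeq2 size factors gave 32 (29 higher, 3 lower) and the 4-class library size 1 (0 higher; median of all genes -0.19). The interaction called 9 genes, 6 without F1 WT normoxia 2, 0 without any other of the 8 libraries, 127 without the F3 libraries and 0 with the 4-class library size. Of the 4 named only Y59E1A.4 passed without F1 WT normoxia 2.

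At F2 no gene passed in either genotype with edgeR. There 166 genes in WT and 837 in hrde-1 had an unadjusted p below 0.05 and DESeq2 called 14 and 58. Y116F11A.1 (-3.28 ± 0.59, adjusted p = 0.133) and Y116A8B.1 (-1.95 ± 0.38, adjusted p = 0.143) had the smallest p in WT. In hrde-1 those were gta-1 (3.66 ± 0.66, adjusted p = 0.101), and K05C4.9 (0.98 ± 0.20, adjusted p = 0.101). hsp-16.1 held 44.5 CPM in F2 WT normoxia and 41.6 in F2 WT hypoxia. The heat shock list did not pass (median 0.08, adjusted p = 0.158). ERGO-1 targets were lower in F2 WT (median -0.79, 0 called and 9 adjusted over the list alone, adjusted p = 5.11e-21, adjusted p = 0.0046 with an estimated correlation) and not in F2 hrde-1 (median 0.35, adjusted p = 0.361). This difference passed the interaction test (median difference 1.14, adjusted p = 1.19e-07, or 0.0857 with an estimated correlation), with the limit on starting levels given for F1. C-type lectins (44 genes, median -0.60, adjusted p = 0.00964) and spermatogenesis genes (median -0.59, adjusted p = 0.0117) were lower in F2 WT. Also lower were collagens (median -0.31, adjusted p = 0.0117) and histones (median -0.19, adjusted p = 0.0442). With an estimated correlation C-type lectins to histones had, in turn, adjusted p = 0.0114, 0.11, 0.165 and 0.242. Oogenic and maternal genes were higher (adjusted p = 0.0352, adjusted p = 0.264 with an estimated correlation). In F2 hrde-1 oogenic and maternal genes (median -0.33, adjusted p = 0.000456), histone modifiers and ribosomal proteins (both adjusted p = 0.0453) and ribosomal RNA (adjusted p = 0.0372) were lower. With an estimated correlation adjusted p was 0.228, or 0.598 for ribosomal RNA.

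Between the genotypes at F2 the interaction also called 0 genes with edgeR, 630 at an unadjusted p below 0.05 and 41 with DESeq2. The smallest p belonged to nhr-229 (1.62) and F31E9.11 (1.34, both adjusted p = 0.487). The F2 WT count was 1 without F2 WT hypoxia 2. The F2 hrde-1 count was 82 without F2 hrde-1 normoxia 1 and 1 without F2 hrde-1 hypoxia 2, and the interaction count was 23 without F2 hrde-1 normoxia 1 and 1 without F2 WT hypoxia 2. Without the F3 libraries these counts were 3, 169 and 61. The fractional values of the F2 WT normoxia libraries set that group apart in its processing.

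At F3 WT the small heat shock protein genes were higher again. hsp-16.49 (2.02 ± 0.43, adjusted p = 0.0356), hsp-16.48 (1.99 ± 0.39), hsp-16.1 (1.84 ± 0.40) and hsp-16.11 (1.77 ± 0.38) rose, 4 of 21 heat shock genes and 7 adjusted over the list alone. So did ptpn-22 (3.35 ± 0.66, adjusted p = 0.03). The F-box genes fbxc-18 (-2.32 ± 0.37, adjusted p = 0.0129) and fbxa-61 (-2.28 ± 0.43) and the ERGO-1 target F39E9.7 (-1.91 ± 0.42) fell. Y105C5B.19, C01G12.12 and ric-4 were at 0 in both hypoxia libraries, at least 11.5-fold, 8.81-fold and 8.52-fold lower than in normoxia. The heat shock list (median 0.63, adjusted p = 4.69e-09, adjusted p = 0.0462 with an estimated correlation) was higher. The ERGO-1 list was lower (median -0.79, 11 adjusted over the list alone, adjusted p = 3.1e-07, adjusted p = 0.0853 with an estimated correlation). C-type lectins (median -0.55, adjusted p = 0.0148), spermatogenesis genes (median -1.14, adjusted p = 0.0105) and F-box genes (2 called and 5 adjusted over the list alone, adjusted p = 0.0105) were lower (0.0462, 0.0853 and 0.242 with an estimated correlation). The F-box median of -0.33 was 0.11 with the 4-class library size. Oogenic and maternal genes (adjusted p = 0.00457), histone modifiers (median 0.31, adjusted p = 0.00974) and small RNA machinery (adjusted p = 0.0148) were higher (0.125, 0.0853 and 0.242 with an estimated correlation). Of all genes 35 passed, 7 higher and 28 lower. The count was 0 without F3 WT normoxia 2, 2 without F3 WT hypoxia 1 and 272 without F3 WT hypoxia 2. hsp-16.48, hsp-16.49 and ptpn-22 passed only in the last of these, C01G12.12 in no fit with a library left out, and ric-4 and Y105C5B.19 not without F3 WT normoxia 2 or F3 WT hypoxia 1. At equal depth the hypoxia libraries would show 8393 and 9450 genes, the normoxia libraries 10484 and 10236. None passed with only the compared libraries in the fit or with the 4-class library size (median of all genes 0.38). In edgeR 1293 had an unadjusted p below 0.05, and DESeq2 called 301.

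**Figure D2:**
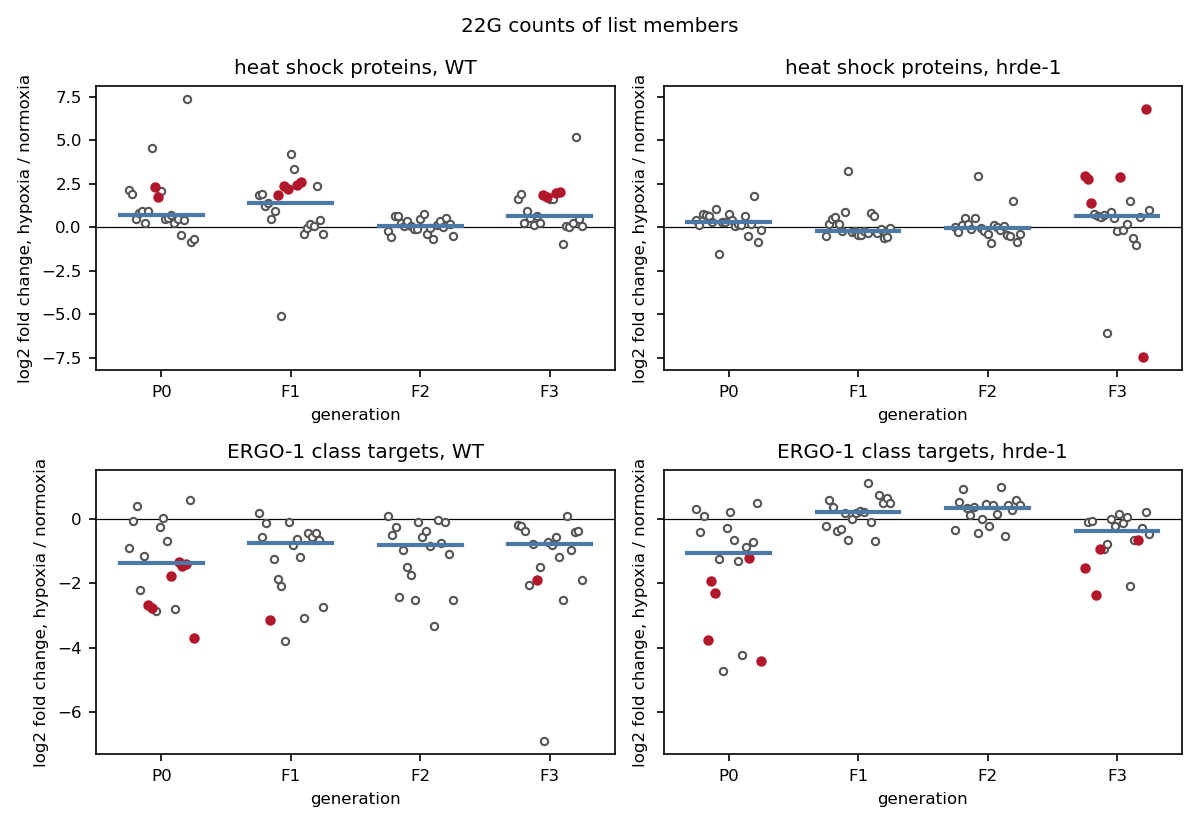
Log2 fold change of 22G counts, hypoxia against normoxia, of each member of the heat shock and ERGO-1 lists by generation and genotype, 1 circle per gene, filled red where edgeR's adjusted p was below 0.05, with a bar at the median. In WT the heat shock medians are 0.72, 1.41, 0.08 and 0.63 from P0 to F3 and the ERGO-1 medians -1.37, -0.73, -0.79 and -0.79; with the 4-class library size the P0 WT ERGO-1 median is 1.33. Genes at 0 in one group are drawn at their fitted fold, which is no bound.

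In the main fit F3 hrde-1 had the most calls of any single generation, 2183 genes (1542 higher, 641 lower). It called 0 when only its own 4 libraries entered the fit. F44E5.4 rose from 3.79 ± 2.75 CPM (SD, n = 2) to 30.1 ± 9.98. hsp-16.41 rose by 2.89 ± 0.80 (adjusted p = 0.0128), among 5 heat shock genes called higher and 1 lower, a list that did not pass as a set (adjusted p = 0.087). A snoRNA gene of the Y105C5A series, Y25C1A.13 and fubl-4 were at 0 in both normoxia libraries and at least 66.6-fold, 29.5-fold and 28.8-fold higher under hypoxia. K08D10.15, Y47D3A.21 and ZC239.21 were at 0 in both hypoxia libraries and at least 26.5-fold, 17.4-fold and 13.6-fold lower. E01G4.5 (-2.37) fell. ERGO-1 targets (4 called lower, median -0.37) and MATH and BATH genes (42 genes, 6 lower and 3 higher) were lower as sets (both adjusted p = 0.015, or 0.655 with an estimated correlation). The count was 3533 without F3 hrde-1 normoxia 1. The 4-class library size called 1643, 1292 of them higher (median of all genes 0.24). It left 2 ERGO-1 targets and 4 MATH and BATH genes lower, and neither list passed (adjusted p = 0.0538 and 0.0636).

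Between the genotypes at F3 the interaction called 1210 genes, 979 more positive in hrde-1, and no list passed. hsp-16.48 (-2.16 ± 0.54, adjusted p = 0.0101) and hsp-16.49 (-1.81 ± 0.58, adjusted p = 0.0425) responded more in WT. gta-1 held 8.86 CPM in WT normoxia, 0 in WT hypoxia, 0.287 in hrde-1 normoxia and 223 ± 187 (SD, n = 2) in hrde-1 hypoxia. It alone of the 6 genes named by the rule passed whichever library was left out. ZC132.10, F56F4.11, bca-2, hsp-70 and Y47D9A.5 passed with at least 1 group at 0. The count was 4 with only the compared libraries in the fit, 761 without F3 WT normoxia 2, 2997 without F3 hrde-1 normoxia 1, 2012 without F3 hrde-1 normoxia 2 and 787 with the 4-class library size.

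Over F1 to F3 in WT, 393 of 8485 genes changed with the hypoxia label, 117 higher and 276 lower. Of the ERGO-1 targets 13 fell, and 15 adjusted over the list alone, with E01G4.5 at -2.55 ± 0.24 (adjusted p = 0.000738, n = 6), W04B5.2 at -2.93 ± 0.38, F52D2.6 at -3.95 ± 0.88 and cel-mir-8199 at -2.35 ± 0.32. The long intergenic genes linc-16 (-3.16 ± 0.56) and linc-12 (-3.13 ± 0.43) fell, as did Y13C8A.1 (-3.60 ± 0.55, adjusted p = 0.00183), Y51A2A.16 (-3.27 ± 0.34, adjusted p = 9.26e-05), R09A8.9 (-3.27 ± 0.52) and W03D2.15 (-3.08 ± 0.41). Among the rises were hsp-16.41 (1.88 ± 0.44, adjusted p = 0.024), memi-1 (1.61 ± 0.23) and memi-2 (1.17 ± 0.19). Others were inos-1 (1.39 ± 0.16, adjusted p = 0.000154), egrh-3 (1.28 ± 0.28) and sgt-1 (1.19 ± 0.19). Of 20 heat shock genes 6 rose, among them hsp-16.1 (1.42 ± 0.34), hsp-16.11 (1.36 ± 0.31), dnj-13 (0.99 ± 0.16) and hsp-110 (0.94). hsp-3 fell (-0.68), with 13 higher and 1 lower adjusted over the list alone. In small RNA pathway genes csr-1 (0.54 ± 0.10), drh-1 (0.56 ± 0.14) and smrc-1 (0.79 ± 0.17) rose. The histone methyltransferase genes set-9 (0.64 ± 0.10) and set-25 (0.43 ± 0.11) rose. The major sperm protein genes msp-40 (-5.38 ± 0.95) and msp-19 (-4.11 ± 0.95) and the sperm gene spe-47 (-0.47 ± 0.08) fell. So did clec-143 (-1.70), fbxc-18 (-1.46), fbxa-61 (-1.37), the histone gene his-57 (-0.84) and rpl-42 (-0.85).

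As a set for F1 to F3 WT, ERGO-1 targets were lower (median -0.74, adjusted p = 1.5e-26, adjusted p = 0.0444 with an estimated correlation). So were F-box genes (10 of 154 lower, median -0.21, adjusted p = 0.000408, adjusted p = 0.107 with an estimated correlation) and C-type lectins (3 of 29 lower, 5 adjusted over the list alone, median -0.33, adjusted p = 0.000881, adjusted p = 0.0592 with an estimated correlation). Spermatogenesis genes (3 of 22 lower, 4 adjusted over the list alone, median -0.44, adjusted p = 0.0204, adjusted p = 0.28 with an estimated correlation) and collagens (28 genes, median -0.30, adjusted p = 0.0354, adjusted p = 0.215 with an estimated correlation) were lower too. Heat shock genes (median 0.96, adjusted p = 1.56e-09, adjusted p = 0.0592 with an estimated correlation) and oogenic and maternal genes (38 genes, median 0.18, adjusted p = 0.00347, adjusted p = 0.0444 with an estimated correlation) were higher. So were small RNA machinery (3 of 68 higher, 5 adjusted over the list alone, adjusted p = 0.00651, adjusted p = 0.0592 with an estimated correlation), histone modifiers (2 of 24 higher, 3 adjusted over the list alone, adjusted p = 0.0204, adjusted p = 0.0592 with an estimated correlation) and ribosomal proteins (72 genes, adjusted p = 0.0204, adjusted p = 0.28 with an estimated correlation). Without the F3 libraries the spermatogenesis list did not pass (adjusted p = 0.888). The F-box median was 0 with the 4-class library size.

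Without the F1, F2 or F3 libraries the F1 to F3 WT count was 45, 80 or 479. Leaving out 1 library gave 212 and 243 (F1 WT normoxia 1 and 2), 193 and 216 (F1 WT hypoxia 1 and 2), 243 and 217 (F2 WT normoxia 1 and 2) and 207 (F3 WT normoxia 2). Of the 12 genes named by the rule all but egrh-3 and hsp-16.41 passed in every such fit. The 4-class library size gave 329 genes, 223 higher and 106 lower, with the median of all genes at 0.19. Of the F-box genes 5 were then lower and 1 higher, and of the small RNA machinery 7 higher.

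In hrde-1, F1 to F3 together called 15 of 8523 genes, 6 higher and 9 lower. No list passed (lowest adjusted p = 0.271). hil-8 (1.16 ± 0.16, adjusted p = 0.00972), the F-box gene fbxa-136 (1.19 ± 0.22), F41H10.12 (1.28 ± 0.25), R11E3.2 (1.24), csp-2 (1.12), a caspase family gene, and C01A2.6 (1.09) rose. emb-1 (-1.5 ± 0.27, adjusted p = 0.0456), nipi-4 (-1.26 ± 0.24), the histone demethylase gene jmjd-3.2 (-1.19 ± 0.22), R02D5.1 (-1.25) and C09G1.3 (-0.75) fell. F44E5.4 (0.75) and F44E5.5 (0.85) and the ERGO-1 list (median 0.15, adjusted p = 0.747) did not pass. The difference from WT was tested only generation by generation, as above. None of the 11 genes named by the rule passed in every fit with a library left out. Without 1 hrde-1 library the count was 5 and 1 (F1 normoxia 1 and 2), 1 and 4 (F1 hypoxia 1 and 2), and 69 and 4 (F2 normoxia 1 and 2). It was 3 (F2 hypoxia 1), 32 (F3 normoxia 2), and 0 and 3 (F3 hypoxia 1 and 2). Without the F1, F2 or F3 libraries it was 0, 9 or 17 (6 shared), with DESeq2 size factors 11 (3 higher, 8 lower) and with the 4-class library size 0.

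**Figure D3:**
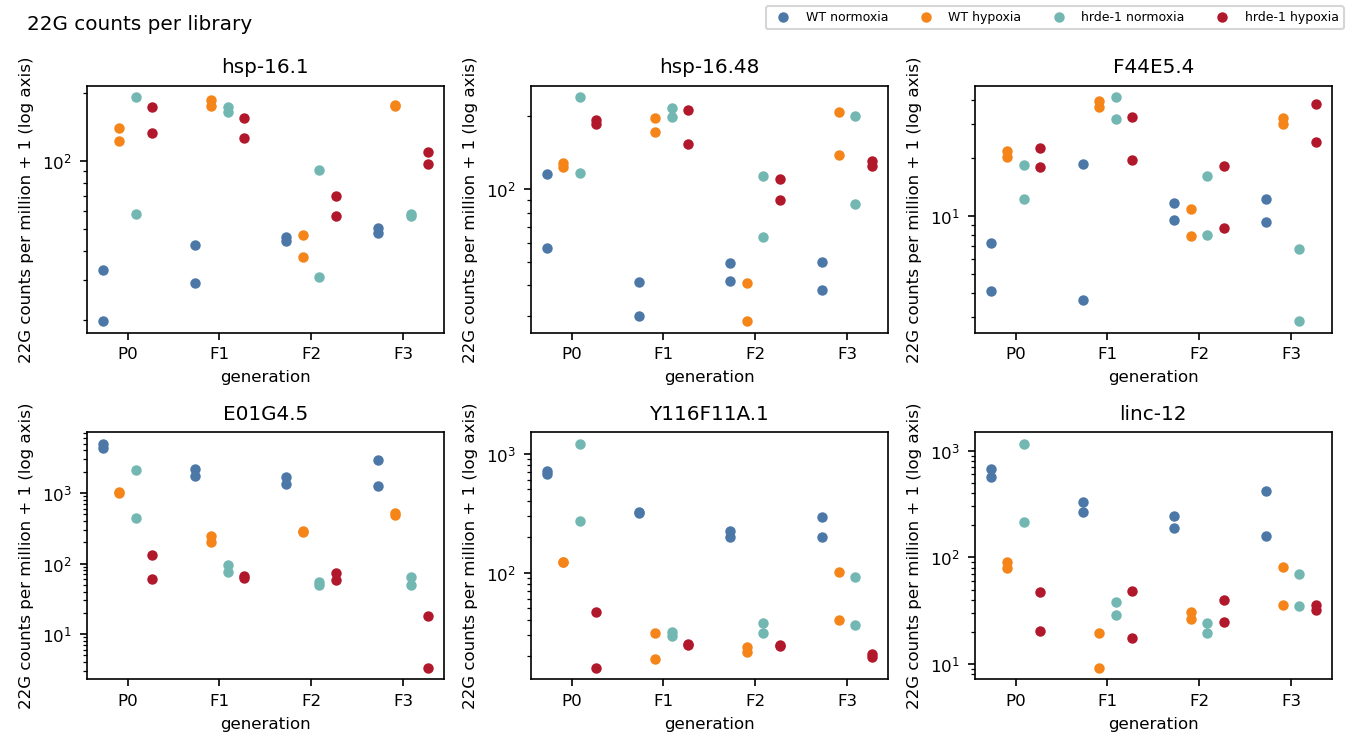
22G CPM plus 1 (log axis) of 6 genes by generation, 1 point per library, coloured by genotype and oxygen label. For hsp-16.1 the F1 WT hypoxia libraries average 180 CPM against 34.8 in F1 WT normoxia and 168 in F1 hrde-1 normoxia, and for E01G4.5 they average 222 against 1960 and 83.8.

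From P0 to later generations of WT few calls were shared. P0 and F1 shared hsp-16.1 and hsp-16.11 as higher (independent lists would share 0.0134) and F39E9.10, linc-12, T16A1.10, Y116A8B.1 and Y116F11A.1 as lower (0.048). P0 and F3 shared the same hsp-16 pair as higher (0.0118) and F39E9.10, F39E9.7, fbxa-61 and Y43F8B.8 as lower (0.149). F1 and F3 shared hsp-16.1, hsp-16.11, hsp-16.48, hsp-16.49 and memi-1 as higher (0.00553) and F39E9.10 and fbxc-18 as lower (0.0249). In hrde-1, P0 and F1 shared F20D6.10 and Y46G5A.6 as lower. P0 and F3 shared 28 lower genes, E01G4.5 and fbxa-61 among them (4.05). Across 10121 genes, which are not independent replicates, the fold changes of P0 WT correlated with those of F1, F2 and F3 WT at r = 0.01, -0.045 and -0.034. F1 with F2, F1 with F3 and F2 with F3 correlated at 0.271, 0.134 and 0.295. In hrde-1 P0 correlated with F1, F2 and F3 at 0.242, 0.059 and 0.092. Under the 4-class library size the P0 correlations with F2 and F3 turned to 0.053 and 0.031, and the 43 calls that P0 shared with a later generation of the same genotype became 10.

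Without hrde-1, 22G RNA differed from WT under normoxia for 2598 of 9279 genes, 1083 higher and 1515 lower in hrde-1 (n = 8 per genotype). The 22G RNA of trp-4 was 501 to 779 CPM per generation in WT normoxia and 0.787 to 2.96 in hrde-1 normoxia (-8.41 ± 0.27, adjusted p = 7.13e-14). K07C6.15 (-8.97 ± 0.32), rimb-1 (-7.54 ± 0.37) and Y38F2AR.12 (-7.49 ± 0.37) were lower in hrde-1 as well. K09D9.12 and K09D9.11 were at 0 in every hrde-1 normoxia library, at least 26.2-fold and 16-fold lower. In the other direction F16B4.4 (9.19 ± 0.40, adjusted p = 1.62e-12), grl-18 (8.60 ± 0.35), Y61A9LA.7 (8.03 ± 0.36), F13D12.8 (7.99 ± 0.32) and C25D7.14 (7.95 ± 0.34) were higher in hrde-1. K06C4.24, at 0 in every WT normoxia library, was at least 8.07-fold higher. All 12 genes passed whichever library was left out. The reported nuclear RNAi targets C38D9.2 (-4.52 ± 0.16, adjusted p = 1.33e-13), F15D4.5 (-3.65 ± 0.13) and bath-45 (-0.77 ± 0.15) all fell, 3 of 3.

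By list, 13 of the ERGO-1 targets fell (16 adjusted over the list alone, median -1.55, adjusted p = 5.43e-05), among them E01G4.5 (-4.21 ± 0.51), F52D2.6 (-4.03) and W04B5.2 (-3.21). F-box genes were lower, 75 of 169 against 10 higher (82 and 10 adjusted over the list alone, median -1.05, adjusted p = 0.000205). Heat shock genes were higher, 10 of 20 (12 adjusted over the list alone, median 0.73, adjusted p = 0.0219), with hsp-16.2 (2.53 ± 0.63), hsp-16.49 (1.62 ± 0.29) and hsp-16.48 (1.56 ± 0.27). Each of these lists had adjusted p = 0.853 with an estimated correlation. In the hypoxia response list ldh-1 (4.52 ± 0.37) was higher. vhl-1 (-3.82) and egl-9 (-1.38) were lower, 3 higher and 2 lower of 13. Among lists that did not pass were 18 lower and 2 higher of 57 histone genes, and 12 and 3 of 34 C-type lectins. Others held 16 and 8 of 66 chemoreceptors, 17 and 7 of 39 MATH and BATH genes, 12 and 9 of 34 collagens, and 8 and 11 of 69 genes of the small RNA machinery. Oogenic genes had 1 lower and 9 higher of 38, and there were 4 and 4 of 24 histone modifiers and 3 and 3 of 39 spermatogenesis genes. Of 3 muscle genes unc-54 (-4.26) and lev-11 (-2.02) fell.

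The genotype comparison called 1295 genes with the 4-class library size, 674 higher and 621 lower, and the median of all genes moved from -0.18 to 0.18. The medians of spermatogenesis genes (-0.12 to 0.01), histones (-0.26 to 0.07) and hypoxia response genes (-0.39 to 0.1) changed sign. Of the ERGO-1 targets 7 were then lower, of the F-box genes 22 lower and 6 higher, and of the nuclear RNAi targets 2 of 3 lower. MATH and BATH genes had 1 lower and 2 higher, C-type lectins 5 and 3, chemoreceptors 10 and 4, collagens 3 and 7, and small RNA machinery 1 and 3. Histone modifiers had 1 lower and 2 higher, hypoxia response genes 1 and 1, muscle genes 1 and 0, and oogenic genes 0 and 0. Without the F3 libraries 3287 genes passed and the C-type lectin list did too (adjusted p = 0.0284).

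**Figure D4:**
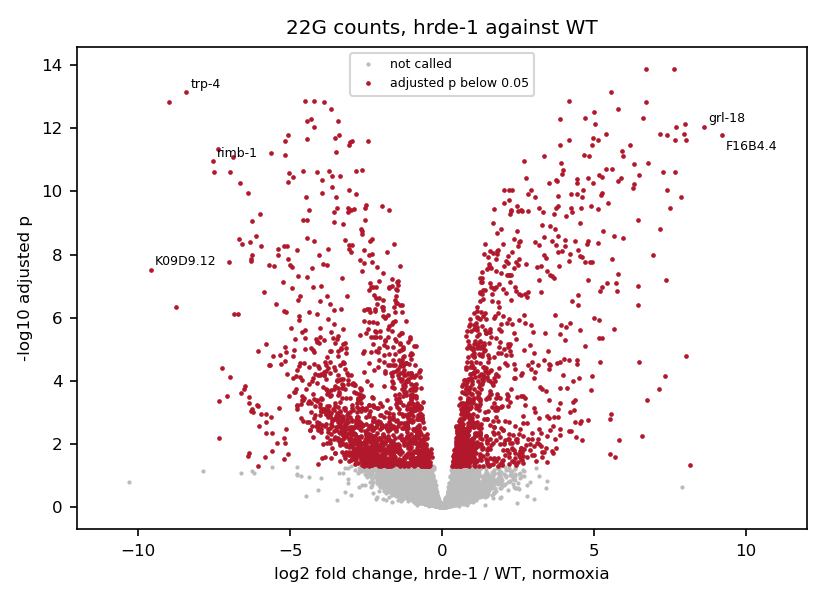
Adjusted p (-log10, vertical axis) against log2 fold change of 22G counts in hrde-1 over WT under normoxia, 1 point per gene tested, red below an adjusted p of 0.05. The 2598 red genes lie on both sides, 1083 to the right and 1515 to the left. Genes at 0 in one genotype, such as K09D9.12, are drawn at their fitted fold, which is no bound. With the 4-class library size 674 lie to the right and 621 to the left.

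Among miRNAs, 53 of 261 changed in P0 WT, 25 higher and 28 lower, against the normoxia libraries flagged below. miR-253-3p (2.68 ± 0.31, adjusted p = 8.8e-07) and miR-77-5p (1.99 ± 0.37) rose. From the let-7 family list, miR-241-5p (1.5 ± 0.24) and both arms of miR-48, miR-48-3p (1.92 ± 0.41) and miR-48-5p (1.46 ± 0.19), rose. So did lin-4-5p (0.93 ± 0.25) and miR-237-5p (1.03 ± 0.30) of the lin-4 family. miR-34-3p (-3.41 ± 1.05), miR-255-3p (-3.15 ± 0.60), miR-62 (-2.65 ± 0.49), miR-41-3p (-2.42 ± 0.78) of the mir-35 family and the muscle miRNA miR-1-3p (-1.34 ± 0.23) fell. miR-2208b-5p was listed at 0 in normoxia. The let-7 family was higher, 6 of 13 members against 1 lower (7 and 1 adjusted over the list alone, median 1.05, adjusted p = 0.00298, adjusted p = 0.122 with an estimated correlation). The mir-35 family had 1 higher and 3 lower of 16 (adjusted p = 0.712). The count was 28 without P0 WT normoxia 2, 32 without P0 WT hypoxia 1, 32 without P0 WT hypoxia 2 and 83 without the F3 libraries. Using the 4-class library size 74 passed, 8 higher and 66 lower, and the median of all miRNAs moved from -0.16 to -0.94. The let-7 median stayed positive at 0.27, with 3 higher and 1 lower, while the mir-58 median went from 0.63 to -0.14. Of the lin-4 family 0 then rose, and of the mir-35 family 6 were lower. By single libraries, miR-34-3p did not pass without normoxia 2, hypoxia 1 or hypoxia 2 (adjusted p up to 0.265), and miR-41-3p and miR-2208b-5p without any of the 4 (up to 0.182 and 0.283).

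In P0 hrde-1, 31 miRNAs changed, 22 higher and 9 lower. miR-70-3p (1.64 ± 0.28, adjusted p = 0.000305), miR-77-5p (1.57), miR-240-3p (1.52), miR-48-3p (1.32), let-7-5p (1.22 ± 0.27) and lin-4-5p (1.04) rose. miR-42-3p (-2.56 ± 0.38, adjusted p = 0.000111), miR-43-3p (-2.36), miR-44-5p (-1.74) and miR-49-3p (-1.59) fell. The let-7 family was higher (7 called, median 0.91, adjusted p = 0.000806). The mir-58 family (2 of 11 higher, median 0.65, adjusted p = 0.0431) was higher too. The mir-44 family (3 of 7 lower, median -1.07, adjusted p = 0.0219) and the mir-35 family (1 lower, median -0.76, adjusted p = 0.0219) were lower. With an estimated correlation their adjusted p were, in turn, 0.0745, 0.246, 0.246 and 0.377. Of the lin-4 family 2 of 3 rose in each genotype at P0. The count was 4 without P0 hrde-1 normoxia 2, 4 without P0 hrde-1 hypoxia 1, 15 without P0 hrde-1 hypoxia 2 and 56 without the F3 libraries. DESeq2 size factors gave 27 (15 higher, 12 lower) and the 4-class library size 32 (4 higher, 28 lower; median of all miRNAs -0.27). Then 1 let-7 member rose, 0 of the lin-4 and mir-58 families did, the mir-58 list did not pass (adjusted p = 0.0627) and 7 of the mir-35 family were lower. miR-42-3p and miR-70-3p passed whichever library was left out. miR-43-3p (-2.99 to -1.41), miR-44-5p (-2.37 to -0.52), miR-48-3p (0.97 to 1.74) and miR-240-3p did not pass without normoxia 2, hypoxia 1 or hypoxia 2. Nor did miR-49-3p without normoxia 2, or miR-77-5p (0.92 to 2.19) without normoxia 1 or hypoxia 1.

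Over F1 to F3 in WT, 29 of 233 miRNAs changed, 15 higher and 14 lower. miR-1829c-3p (1.61 ± 0.34), miR-1829b-3p (1.54 ± 0.33), miR-250-5p (1.18 ± 0.22), miR-253-3p (1.15 ± 0.14, adjusted p = 5.85e-05) and miR-237-5p (1.02), 1 of 3 in the lin-4 family, rose. miR-44-5p (-1.64 ± 0.23), miR-42-3p (-1.59 ± 0.20, adjusted p = 5.85e-05), miR-34-3p (-1.55) and miR-788-5p (-1.53) fell. The mir-35 family, which is abundant in eggs and embryos, had 5 of 16 members lower, miR-37-3p (-0.98) and miR-35-3p (-0.83) among them, and miR-41-5p (0.78) higher (7 and 1 adjusted over the list alone, median -0.60, adjusted p = 0.0017, adjusted p = 0.278 with an estimated correlation). The mir-58 family was higher (3 of 10, median 0.33, adjusted p = 0.0417, adjusted p = 0.278 with an estimated correlation). Using the 4-class library size 42 passed, 9 higher and 33 lower. The median of all miRNAs moved from -0.08 to -0.35 and the let-7 median from 0.18 to -0.1, with 3 let-7 members lower, and 1 of the mir-58 family was higher (adjusted p = 0.0613 for the list). Without the F2 libraries 10 passed. miR-34-3p passed only without F3 WT hypoxia 1 or F3 WT hypoxia 2 when a library was left out (adjusted p up to 0.112). miR-788-5p did not pass without F1 WT normoxia 2, F1 WT hypoxia 2, F3 WT normoxia 2 or any F2 WT library (up to 0.104).

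In F1 to F3 hrde-1 edgeR called 0 of 237 miRNAs, with 33 at an unadjusted p below 0.05 and 15 called by DESeq2. miR-41-5p (-1.01) and miR-78 (-0.99, both adjusted p = 0.0937) had the smallest p. The mir-35 family was lower as a set (0 called, 4 adjusted over the list alone, median -0.55, adjusted p = 0.000129, adjusted p = 0.43 with an estimated correlation). The count was 6 without F2 hrde-1 normoxia 1, 1 without F3 hrde-1 normoxia 2 and 2 without the F3 libraries. Between genotypes under normoxia 57 of 248 miRNAs differed, 26 higher and 31 lower. miR-253-3p (1.86 ± 0.21, adjusted p = 5.66e-06) and miR-250-5p (1.19 ± 0.26) were higher in hrde-1. miR-52-3p (-2.41 ± 0.64), miR-49-5p (-2.33), miR-34-3p (-2.14), miR-43-3p (-1.92), miR-36-3p (-1.60) and miR-42-3p (-1.57) were lower. The mir-35 family was lower in hrde-1 (7 lower and 1 higher, median -0.96, adjusted p = 0.0108, adjusted p = 0.568 with an estimated correlation). The mir-58 family was higher (4 of 10, median 0.62, adjusted p = 0.0454, adjusted p = 0.243 with an estimated correlation). The let-7 family did not pass (2 higher, adjusted p = 0.0697). The 4-class library size called 53, 5 higher and 48 lower (median of all miRNAs from -0.15 to -0.39). The mir-58 family then had 0 higher and 1 lower (adjusted p = 0.0921) and let-7 0. With a library left out miR-34-3p passed only without F2 hrde-1 normoxia 1 (adjusted p up to 0.162). miR-43-3p did not pass without F1 WT 1, F3 WT 2, P0 hrde-1 1, F1 hrde-1 2 or F2 hrde-1 2 under normoxia (up to 0.0786), and miR-49-5p without F1 WT 1, P0 hrde-1 1 or F3 hrde-1 1 (up to 0.069). The count was 32 without P0 hrde-1 normoxia 1 and 33 without the P0 libraries. The mir-51, mir-64 and mir-2 families, tissue miRNAs and miRNAs of stress and ageing passed in no comparison.

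**Figure D5:**
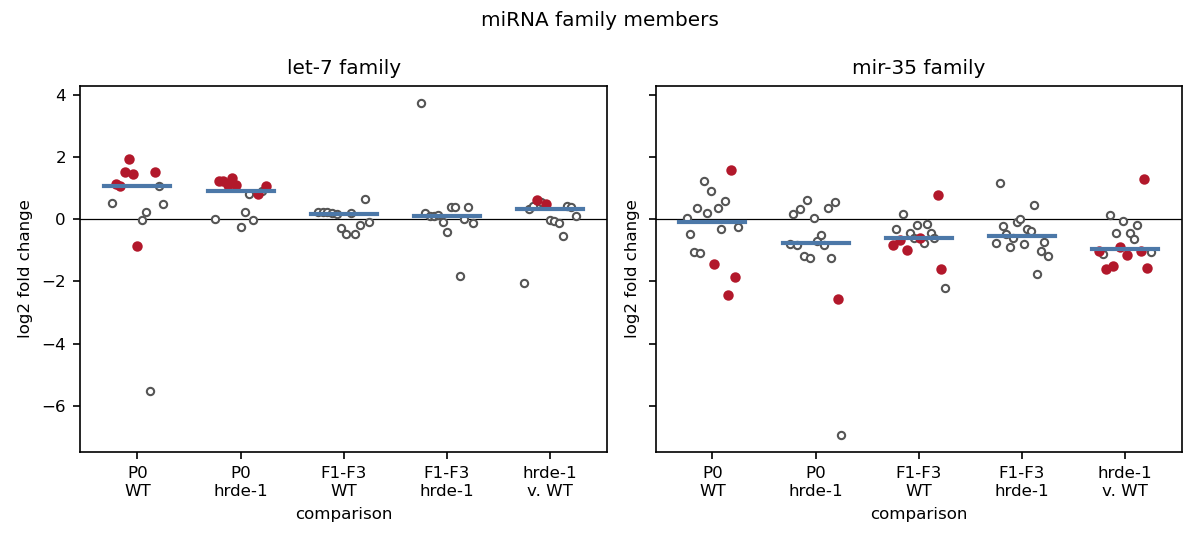
Log2 fold change of each let-7 and mir-35 family miRNA in 5 comparisons (hypoxia against normoxia in 4, hrde-1 against WT under normoxia in the fifth), 1 circle per miRNA, filled red where edgeR's adjusted p was below 0.05, with a bar at the median. The let-7 median is 1.05 in P0 WT and 0.91 in P0 hrde-1, and the mir-35 median is -0.60 in F1 to F3 WT and -0.96 between genotypes. With the 4-class library size the let-7 median of F1 to F3 WT turns to -0.1.

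In P0 WT 9 of 7978 piRNAs passed with edgeR, 3 higher and 6 lower, in a fit that recovered 1 and 2 of 100 simulated piRNAs changed by a log2 of 1 and 2. DESeq2 called 60 in P0 WT, 101 in P0 hrde-1 and 132 in F1 to F3 WT. piR-cel-15840 (4.45 ± 0.61, adjusted p = 0.000126) and piR-cel-15879 (2.80 ± 0.37) rose. piR-cel-1507 (-2.32 ± 0.37) fell and piR-cel-7295 was listed at 0 under hypoxia. In P0 hrde-1 8 passed, all higher, with piR-cel-4133 and piR-cel-8788 listed at 0 in normoxia, and 3 without P0 hrde-1 normoxia 2. The P0 WT count was 17 without P0 WT normoxia 1, 14 without P0 WT hypoxia 1 and 17 without P0 WT hypoxia 2. Without the F3 libraries the P0 WT and hrde-1 counts were 190 and 102. In F1 to F3 WT piR-cel-16548 alone passed (0.93 ± 0.11, adjusted p = 0.00207). It did so in every fit with a library left out but not without the F1, F2 or F3 libraries, where edgeR called 0. In F1 to F3 hrde-1 edgeR called 0 of 6914 (471 at an unadjusted p below 0.05, DESeq2 22). The smallest p were those of piR-cel-15882 and piR-cel-7780 (adjusted p = 0.694). The count was 1 without F3 hrde-1 normoxia 2 or F3 hrde-1 hypoxia 2. Between genotypes 180 of 6909 piRNAs differed, 85 higher and 95 lower in hrde-1. piR-cel-6692 (2.06 ± 0.48, adjusted p = 0.0208) was higher, with piR-cel-26697 listed at 0 in WT, and piR-cel-1726 and piR-cel-4249 listed at 0 in hrde-1. Under normoxia, leaving out a WT library gave 106 and 100 (P0 WT 1 and 2), 109 (F1 WT 2), 103 and 111 (F2 WT 1 and 2) or 90 and 92 (F3 WT 1 and 2). Leaving out an hrde-1 library gave 101 (P0 hrde-1 1), 89 (F1 hrde-1 2), 85 (F2 hrde-1 2) or 467 (F3 hrde-1 2). Leaving out P0 gave 42 and leaving out F3 605. The 4-class library size gave 105 (70 higher, 35 lower), with the median of all piRNAs at -0.39.

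Of the snoRNAs, T26A8.6 (2.35 ± 0.43, adjusted p = 0.0015) and R07G3.16 (2.05 ± 0.56) rose and Y77E11A.21 (-2.78 ± 0.56) and T25D10.11 (-1.74 ± 0.43) fell in P0 WT, where 9 of 339 passed, 6 higher and 3 lower. The count was 1 without P0 WT normoxia 2, P0 WT hypoxia 1 or P0 WT hypoxia 2, and 19 without the F3 libraries. It was 255, all higher, with the 4-class library size, which moved the median of all snoRNAs to 1.75 and T25D10.11 to 0.01. No snoRNA passed in P0 hrde-1, F1 to F3 WT or F1 to F3 hrde-1 with edgeR (8, 15 and 26 at an unadjusted p below 0.05) or DESeq2 (0, 0 and 0). The smallest p belonged to T25C12.12 (-4.13, adjusted p = 0.327) and F19G12.14 (-1.37), to C07A9.14 (0.66) and T25D3.8 (-0.79, adjusted p = 0.729), and to JC8.15 (1.39) and T21F2.3 (-0.88, adjusted p = 0.52). Between genotypes 41 of 335 snoRNAs differed, 19 higher and 22 lower. T07D4.7 (5.75 ± 0.37, adjusted p = 1.37e-12) and Y51A2D.40 (3.16 ± 0.57) were higher in hrde-1, and Y102A11A.16 (-2.64 ± 0.36) and F48F5.7 (-2.58 ± 0.31) lower, in every fit with a library left out. That count was 25 without F1 WT normoxia 1, 27 without F3 WT normoxia 2, and 27 and 26 without F1 hrde-1 normoxia 1 and 2. It was 26 without the F3 libraries and 20 (15 higher, 5 lower) with the 4-class library size (median of all snoRNAs 0.23).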

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

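The tests on the P0 WT normoxia libraries were chosen only after their 22G shares were seen, as were all fits without one generation. The tests on the F3 hrde-1 calls and the splits of the samples were fixed before their results were seen.

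The 22G share of the P0 WT normoxia libraries was 7.71% ± 2.21 (SD, n = 2), -27.1 points from the 34.8% ± 1.48 (SD, n = 6) of F1 to F3 WT normoxia (32.8% to 36.7%), while P0 hrde-1 normoxia held 38.5% ± 2.53. Lower depth is argued against, since the shallower of those libraries held 6562482 counts over the 4 classes and the deepest of the other 30 held 5887258. Hypoxia at P0 is argued against as the whole cause, since the -27.1 points lie in animals that were not exposed, and whether it raised P0 WT hypoxia by part of its 7.41 points above F1 to F3 WT normoxia was not tested. A lower capture of molecules with a 5′ triphosphate stays open: against miRNA, 22G RNA was at 0.116 and 0.075 where the lowest of the other 30 libraries had 0.222, and piRNA (0.109 and 0.126, others 0.104 to 0.254) lay below all others in 0 of the 2 libraries. It cannot be told apart from another difference in preparation, because the snoRNA to miRNA ratio (0.0222 and 0.0175, lowest other 0.0277) also lay below all others and the 5′ ends of the snoRNA reads are not known.

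At F3 in hrde-1, edgeR called 2183 genes between hypoxia and normoxia. The F3 hrde-1 normoxia 2 library alone is argued against as the source, since 2677 genes passed without it, and 3533 without F3 hrde-1 normoxia 1. Random loss of molecules in the normoxia libraries might contribute: of 4474 genes with at least 20 CPM in F1 and F2 hrde-1 normoxia, 141 and 392 were at 0 in the F3 libraries and 59 in both, 2.3 times the 25.6 that independence gives, a value between those for random loss and for loss of the same genes. A change on the hypoxia side also stays open, with 510 genes called between F3 and the earlier descendants in hrde-1 hypoxia, 1953 in hrde-1 normoxia, 24 in WT hypoxia and 0 in WT normoxia. Which side departed, and whether through the worms or the libraries, cannot be told apart with 2 libraries per group.

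The response to hypoxia differed between WT and hrde-1 by the interaction test for 6 genes at P0, 9 at F1 and 1210 at F3. At P0 the differences were 3.75 in T09B4.14, 3.23 in T28B8.1, 3.01 in cel-mir-5592-2 and -2.91 in prx-11. At F1 they were 3.12 in B0524.4, 2.75 in Y26G10.5, 2.16 in Y59E1A.4 and -2.92 in hsp-16.49. With the 4-class library size only prx-11 (-5.17) passed, the other P0 genes at 1.35, 0.88 and 0.63. Lists differing at P0 were spermatogenesis genes (camera adjusted p = 2.78e-05, median difference 1.03, or -0.75 with the 4-class library size) and histones (3.03e-05). Others were ribosomal RNA (0.00231) and heat shock proteins (0.0167, 0.105 without the F3 libraries), at 0.378 and 0.512 with an estimated correlation. At F1 they were heat shock proteins and ERGO-1 targets (both 9.37e-12, with different starting levels) and spermatogenesis genes (0.000648). Also at F1 were oogenic and maternal genes (0.0155, adjusted p = 0.187 with an estimated correlation), and small RNA machinery, ribosomal proteins, lipid metabolism and F-box genes (each 0.0413, adjusted p = 0.172 to 0.374 with an estimated correlation). At F2 they were ERGO-1 targets (1.19e-07), oogenic and maternal genes (2.86e-05) and histone modifiers (0.0102), each at 0.0857 with an estimated correlation. Also at F2 were small RNA machinery, ribosomal proteins, collagens and F-box genes (each 0.0434, 0.174 to 0.509 with an estimated correlation).

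Splits of the same libraries within generations were compared with the real split. A random grouping of these libraries is argued against for 22G RNA. There 1 of 60 splits, the real one, gave as many calls. This held in F1 to F3 WT (393, highest other 2) and hrde-1 (15, highest other 1) and between genotypes (2598, highest other 870). For miRNA it was 1 of 100 in F1 to F3 WT (29, highest other 5) and between genotypes (57, highest other 21), and for snoRNA 1 of 100 between genotypes (41, highest other 13). For piRNA it was 1 of 40 between genotypes (180, highest other 0). It was also 1 of 40 in F1 to F3 WT (1, highest other 0), but there any single call would give that, so a random grouping is left open. Where the real split called 0, every split gives as many by construction, so these counts say nothing about chance: miRNA in F1 to F3 hrde-1 (100 of 100, highest other 2), piRNA in F1 to F3 hrde-1 (40 of 40, highest other 0) and snoRNA in F1 to F3 WT and hrde-1 (100 of 100 each, highest other 6 and 7).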

How the results depend on the processing

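Across the alternatives, results for named genes, lists, class shares and correlations of fold changes stayed on their side of any threshold and in their direction 3126 times, were no longer past it 672 times, were newly past it 61 times and reversed 35 times, 3 of these correlations. Another 7 values, all correlations, moved. Counts of calls stayed within 1.5 times 309 times and moved further 212 times. The shallowest libraries held 438436 (P0 WT normoxia 2) and 473558 (F2 hrde-1 normoxia 2) 22G counts, and at P0 WT 5% and 11% of simulated 22G changes of a log2 of 1 and 2 were recovered. For every value that moved, the cause was not tested, except that fits of fewer libraries hold fewer samples. Alternatives that leave out a generation or keep genes of at least 10 CPM were chosen after seeing the data.

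Without a filter on low counts 22G RNA gave 163, 92, 67 and 229 calls in P0 to F3 WT, 146, 126 and 65 in P0 to F2 hrde-1, 34, 83 and 54 in the interactions of P0 to F2, 735 in F1 to F3 WT and 137 in F1 to F3 hrde-1. It gave 16 miRNAs in F1 to F3 hrde-1, and 21, 13, 64, 1 and 385 piRNAs in P0 WT, P0 hrde-1, F1 to F3 WT, F1 to F3 hrde-1 and between genotypes, and F44E5.4 in F2 hrde-1 was -0.01. DESeq2 gave 124, 69, 14 and 301 in P0 to F3 WT, 140, 122 and 58 in P0 to F2 hrde-1, 16, 107 and 41 in the interactions, 657 and 141 in F1 to F3 WT and hrde-1, 15 and 88 miRNAs in F1 to F3 hrde-1 and between genotypes, 60, 101, 132, 22 and 876 piRNAs in the order above, and 21 snoRNAs in P0 WT. DESeq2 size factors gave 14 genes in the F1 interaction, and the F2 interaction of hrde-1 was 0.02 with DESeq2 and 0.01 with its size factors.

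With the sum of the 4 classes as library size 22G RNA gave 7496, 9, 1 and 0 in P0 to F3 WT, 41 and 1 in P0 and F1 hrde-1, 3919, 0 and 787 in the interactions of P0, F1 and F3, 0 in F1 to F3 hrde-1 and 1295 between genotypes. It gave 5 miRNAs in F1 to F3 hrde-1, 5, 30 and 105 piRNAs in P0 hrde-1, F1 to F3 WT and between genotypes, 255 and 20 snoRNAs in P0 WT and between genotypes, and 10 calls shared between P0 and later generations. Reversed values were 0.03, 0.08 and 0.05 for hrde-1 in P0 hrde-1, the F2 interaction and the genotype comparison, -0.03 for F44E5.5 in F1 hrde-1, 0 for F44E5.4 in F2 hrde-1, 0.01 for the snoRNA T25D10.11, and correlations of 0.053 and 0.031 for P0 with F2 and F3 WT, the former also 0.001 over genes above the median abundance. With only the compared libraries in the fit 22G RNA gave 785, 389, 98 and 0 in P0 to F3 WT, 229, 386, 1 and 0 in P0 to F3 hrde-1 and 31, 372, 1 and 4 in the interactions, with 141 miRNAs, 145 piRNAs and 95 snoRNAs in P0 WT, 0 piRNAs in P0 hrde-1, and hrde-1 at 0 in F2 hrde-1.

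Without the F3 libraries 22G RNA gave 207, 77 and 3 in P0 to F2 WT, 320, 272 and 169 in P0 to F2 hrde-1 and 20, 127 and 61 in the interactions, with 83, 56 and 2 miRNAs in P0 WT, P0 hrde-1 and F1 to F3 hrde-1, 190, 102, 0 and 605 piRNAs in P0 WT, P0 hrde-1, F1 to F3 WT and between genotypes, and 19 and 26 snoRNAs in P0 WT and between genotypes. F44E5.4 was then -0.05 in F2 hrde-1, and F44E5.4 and F44E5.5 were -0.31 and -0.05 in F1 to F3 hrde-1. Without the F1 libraries F1 to F3 gave 45 genes in WT, 0 in hrde-1 and 0 piRNAs in WT, and without the F2 libraries 80, 9 and 0, with 10 miRNAs in WT and 1 and 2 snoRNAs in WT and hrde-1. Without P0 33 miRNAs and 42 piRNAs passed between genotypes. Genes of at least 10 CPM gave 1354 in F3 hrde-1, 14 and 688 in the F1 and F3 interactions and 1 in F1 to F3 hrde-1. With an estimated correlation 17 of 329 list tests passed instead of 82, while fry gave 89.

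The replicate numbers did not pair the libraries (correlations of deviations from -0.038 to 0.045). With the replicate number as a block 22G RNA gave 26 in F1 WT, 3 in F2 WT, 1 in F2 hrde-1, 20 in the F1 interaction and 3 in F1 to F3 hrde-1, with 35 miRNAs between genotypes, 1 and 72 piRNAs in P0 hrde-1 and between genotypes, 1 class share and 66 shared calls, and it moved no other count of calls by more than 1.5 times.

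Leaving out each library in turn, where the lone library left is assumed to vary like the other groups, gave 22G counts of 27 to 51, 0 to 8, 0 to 1 and 0 to 272 in P0 to F3 WT, 20 to 60, 2 to 12, 0 to 82 and 1522 to 3533 in P0 to F3 hrde-1, 0 to 7, 0 to 6, 0 to 23 and 761 to 2997 in the interactions, 193 to 519 in F1 to F3 WT and 0 to 69 in F1 to F3 hrde-1. miRNA counts were 28 to 40 in P0 WT, 4 to 34 in P0 hrde-1, 0 to 6 in F1 to F3 hrde-1 and 32 to 61 between genotypes. piRNA counts were 9 to 17, 3 to 9, 0 to 1 and 85 to 467 in the same comparisons, snoRNA counts 1 to 8 and 0 to 1 in P0 WT and hrde-1 and 25 to 51 between genotypes, and 1 to 3 class shares had an unadjusted p below 0.05. F44E5.4 ranged from -0.47 to 0.05 in F2 WT, -0.64 to 0.84 in F2 hrde-1 and -0.45 to 1.03 in the F2 interaction. F44E5.5 ranged from -0.18 to 0.54, -0.14 to 0.49 and -1.32 to 0.79 in P0, F1 and F2 hrde-1 and from -0.77 to 1.34 in the F2 interaction. hrde-1 ranged from -0.34 to 0.01 in F3 hrde-1 and -0.11 to 0.03 in the F2 interaction, and the snoRNA T25C12.12 from -5.52 to 1.38 in P0 hrde-1.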

Other observations

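The resemblance to hrde-1 was noticed on plots of single genes, and the pattern was chosen for that reason. Its tests were written before their values were computed. They took the place of tests on the rise of heat shock genes in F1 WT, which had been computed already: the 13 members other than hsp-16 and F44E5 genes had a median of 0.4, 9 positive and 1 called (camera unadjusted p = 7.96e-06, p = 0.014 with an estimated correlation).

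At F1, the 22G RNA of genes picked for this resemblance lay nearer to hrde-1 normoxia in WT hypoxia than in WT normoxia. E01G4.5 held 1960 ± 293 CPM (SD, n = 2) in WT normoxia, 222 ± 27.8 in WT hypoxia and 83.8 ± 13.9 in hrde-1 normoxia. Y116F11A.1 held 317 ± 4.13, 24.0 ± 8.73 and 29.4 ± 1.85, and linc-12 298 ± 47.2, 13.3 ± 7.22 and 32.5 ± 6.31. The small heat shock genes moved the other way: hsp-16.1 held 34.8 ± 9.55, 180 ± 7.93 and 168 ± 6.98. hsp-16.48 held 34.6 ± 8.22, 184 ± 17.1 and 207 ± 11.8. At F2 hsp-16.1 (44.5, 41.6 and 60.4) and hsp-16.48 (44.6, 33.7 and 87.4) did not show this, nor did hsp-16.1 at F3 (48.5, 174 and 56.7). trp-4, whose 22G RNA was nearly lost in hrde-1, did not follow, with 751 ± 43.9 CPM in F1 WT normoxia and 820 ± 22.5 in F1 WT hypoxia.

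Of 276 genes lower in F1 to F3 WT hypoxia and 1284 lower in F1 to F3 hrde-1 normoxia, both against WT normoxia, 153 were shared (independent lists would share 43.1), with 28 going the other way. Of the genes higher in WT hypoxia and the 752 higher in hrde-1 42 were shared (10.6), with 2 going the other way. Because both comparisons use the same WT normoxia libraries, the controls were divided. Then 34 of 56 and 40 of 91 lower genes were shared (4.36 and 6.58 by independence), and 8 of 12 and 8 of 23 higher genes (0.585 and 1.09). The correlation of log2 fold changes over 8230 genes, which are not independent replicates, was 0.356 with a covariance of 0.364. Over 10 simulated draws of unchanged groups the mean was 0.507 (0.491 to 0.524) with a covariance of 0.126, and the difference of the covariances was 0.238.

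Shared control libraries stay open as the cause. Unchanged groups sharing them correlated at 0.507 in simulation, above the observed 0.356, although their covariance was lower (0.126 against 0.364). With the controls divided the correlation was 0.147 and 0.127. What the 2 WT normoxia libraries of a generation have in common would remain there, all of it if they are technical repeats. Worms of the hrde-1 strain mixed into the WT hypoxia samples are argued against. The 76 genes at least 32-fold higher in hrde-1 reached a median of -0.0401% of their hrde-1 level in WT hypoxia (quartiles -0.505% and 0.362%). A general loss of 22G RNA that depends on HRDE-1 may contribute but cannot be told apart from a loss at some targets: the 88 genes at least 32-fold lower in hrde-1 had a median of -0.39 (quartiles -0.98 and -0.1), between the bounds set for either, with 11 called lower and 0 higher. That WT animals with the hypoxia label at F1 to F3 share part of the hrde-1 profile is a hypothesis, found and tested on the same libraries.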
